A study of Mus musculus with 14 samples.

How the data were processed

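Polyadenylated RNA was sequenced from mouse oocytes that overexpressed Rnaseh1, mCherry as the control, or Rnaseh1 together with Supt6. Reverse transcription used SuperScript II, the cDNA was amplified with KAPA HiFi polymerase and the libraries were built with a Vazyme TD503 kit, per the labels' protocols. The 14 libraries make up 7 groups of 2. A first table holds oocytes with a non-surrounded nucleolus (NSN) and with a surrounded nucleolus (SN), each with mCherry or Rnaseh1. A second table, the rescue set, holds mCherry, Rnaseh1 and Rnaseh1 plus Supt6, and its labels give no oocyte stage. The labels do not say whether the 2 libraries of a group came from different animals, pools of oocytes or library preparations, so every p-value measures the spread between libraries only.

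The deposited values are transcripts per 1000000 transcripts (TPM) per gene, one column per library, with 35389 gene identifiers in the NSN and SN table and 35341 symbols in the rescue table. Trim Galore 0.6.7, STAR 2.7.0d, RSEM 1.3.3, DESeq2 and the mm10 genome are named without their roles, per the submitters' processing notes. TPM keeps no depth, so the number of reads behind a value is not known and no counting error is given. An exact 0 is reported as listed at 0. Of the identifiers of the first table, 35319 were paired with a symbol and 70 were not. The GENCODE M21 annotation of the same assembly (GRCm38) held 34611 of these identifiers with their version and 34257 of the rescue symbols. It gave the coordinates and the transcript GC content and length. For 27 symbols, the rescue values had more than 2 decimals, 22 of them shared by several identifiers. Neither table had genes of the mitochondrial chromosome.

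Each table was fitted on its own with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) in R 4.3.3 on log2(TPM + 1), with a mean for every group and one estimate of the spread for all groups of a table. Genes with a TPM of at least 1 in at least 2 libraries of the table were tested, and the Benjamini-Hochberg adjusted p had to be under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. "Rose" and "fell" are used for genes past that threshold, and adjusted p-values of genes are limma's. Fixed gene lists, 23 in number, were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation (statmod 1.5.0), two-sided, with adjustment over the lists of a comparison. Lists with fewer than 3 tested genes got counts only. Members past the gene threshold were counted after adjustment over all genes and after adjustment over the list alone. A list's position is given as its median log2 fold change and as that median minus the median of all tested genes.

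The fit, the filter, the lists, the comparisons and the alternatives were chosen before the data were examined, except where a choice is described as made later. The genes named were Rnaseh1 and Supt6, then up to 10 per direction with the largest log2 fold change among genes past the threshold whose libraries did not overlap between the groups and whose higher group had a mean TPM of at least 5, leaving out gene models. Where fewer than 5 genes passed in a direction, the genes with the smallest p up to 5 were taken. In each list described, up to 4 members with the smallest p were taken. The values of replication-dependent histones, and of other genes with near-identical copies or processed pseudogenes, are uncertain because RSEM divides reads between such copies. Strand use in the counting is not stated, so antisense genes such as Atad3aos cannot be told apart from their partners.

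Sets of 200 genes with the smallest p in each direction of the SN, NSN and stage comparisons were tested in the rescue table with camera, over genes tested in both tables. The agreement of Rnaseh1 effects was given as Pearson's r and Spearman's rho across the 11800 genes of both tables, without a p since genes are not independent replicates. Comparisons within the rescue set share libraries, so 100 draws of unchanged groups were simulated for the value that sharing alone gives. The script was tested on simulated data with 200 changed genes per comparison. In the rescue set it recovered 37.0% of genes changed by 1 on the log2 scale and 89.0% of those changed by 2. In the SN comparison it recovered 0% at 1 and at 2, and 46.5% at 3, so with 200 changed genes only very large changes passed there. The adjusted cut-off depends on how many genes change, and simulated errors were independent between genes. The recovery under a broader change was not simulated.

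The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of TPM at least 5, median centring over genes with a mean TPM of at least 10, quantile normalization, rescaling without the overexpressed genes, a minimum log2 change of 1, groups fitted alone, robust eBayes, the replicate number as a block, set sizes of 100 and 500, and each library left out in turn. Removal of a loess trend (span 0.5) on transcript GC content, library weights, and a fit without both set-apart libraries were added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All columns of both tables were used.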

Results

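Messenger RNA was measured in mouse oocytes that overexpressed Rnaseh1, whose protein cleaves the RNA strand of RNA:DNA hybrids (R-loops), or the red fluorescent protein mCherry as the control. The first set of 8 libraries compared both treatments in oocytes with a non-surrounded nucleolus (NSN), an earlier and transcribing state, and with a surrounded nucleolus (SN), a later and largely silent one. The second set of 6 libraries, called the rescue set, held mCherry, Rnaseh1, and Rnaseh1 together with Supt6, a histone chaperone that travels with elongating RNA polymerase II; its labels name no stage. Every group had 2 libraries, and values are in transcripts per 1000000 transcripts (TPM), given as the mean ± SD of n = 2. Depth is not known from TPM. The number of genes with a TPM of at least 1 ran from 10036 to 11811 per library in the NSN and SN set and from 10892 to 12230 in the rescue set.

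Rnaseh1 (ENSMUSG00000020630.9, chromosome 12, 28649602 to 28659589, GRCm38) was highest in the oocytes that received it. In NSN oocytes it stood at 487 ± 365 TPM with Rnaseh1 against 122 ± 20.5 with mCherry, and in SN oocytes at 1222 ± 196 against 106 ± 35.4. The log2 fold changes were 1.76 (SE 0.57) and 3.55 (SE 0.57). Neither passed over all genes, with limma's adjusted p of 0.76 and 0.41, and both passed when adjusted over the list alone, that is over the 2 overexpressed genes. In the rescue set Rnaseh1 rose from 119 ± 7.69 to 934 ± 437 TPM, a log2 fold change of 2.87 (SE 0.28, adjusted p = 8.9e-05), and reached 2144 ± 179 with Supt6 added, 1.28 (adjusted p = 0.0062) above Rnaseh1 alone. Supt6 (ENSMUSG00000002052.6, chromosome 11, 78206746 to 78245987) rose from 2.78 ± 0.325 TPM with Rnaseh1 to 24.6 ± 5.08 with both, a log2 fold change of 2.75 (adjusted p = 6e-05). With Rnaseh1 alone Supt6 was at -0.16 (SE 0.23, adjusted p = 0.57) against mCherry and did not pass, while removal of a trend with GC content turned that value to 0.92 and past the threshold. In the NSN and SN set Supt6 stayed between means of 1.65 and 4.58 TPM.

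**Figure D1:**
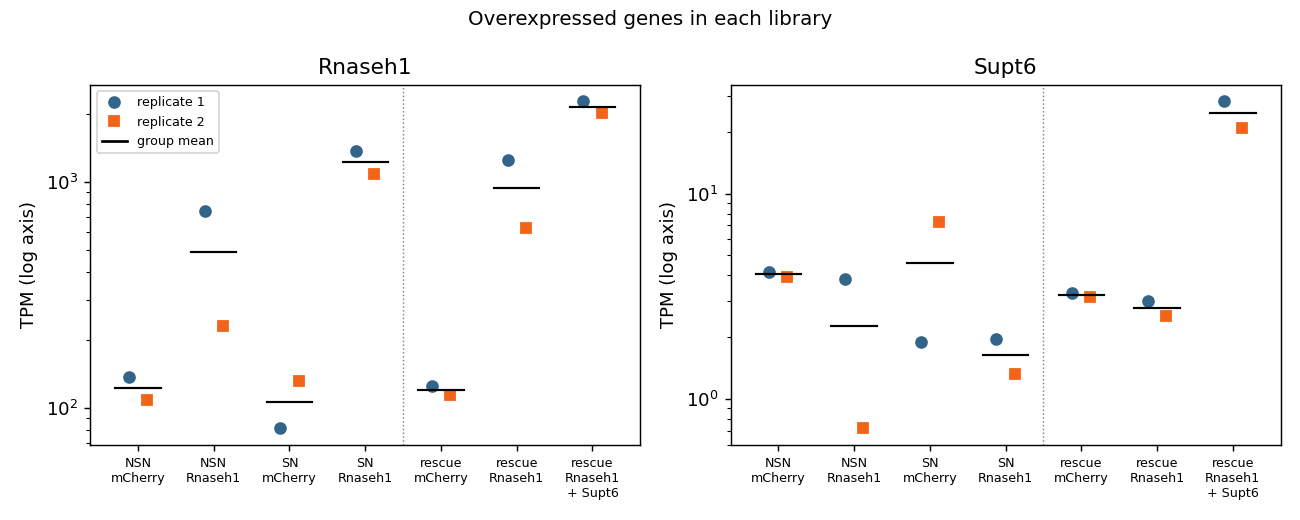
Rnaseh1 and Supt6 in every library, in TPM on a log axis, one point per library and a bar at each group mean. Every library given Rnaseh1 lies above every mCherry library of its set, the lowest at 229 TPM in NSN oocytes, and Supt6 reaches 21.0 and 28.2 TPM in the libraries that received it.

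Libraries of 2 groups of the NSN and SN set, NSN Rnaseh1 and SN mCherry, differed more than those of any other group. Across genes, libraries of one group correlated at r = 0.865 to 0.967 in the NSN and SN set and libraries of different groups at 0.762 to 0.969, against 0.974 to 0.989 and 0.813 to 0.971 in the rescue set. NSN Rnaseh1 replicate 2 and SN mCherry replicate 2 lay at opposite ends of the first principal component, at 113 and -91, with the other 6 libraries from -40.7 to 39.9. The SD across genes of the difference between the replicates was 1.28 on the log2 scale for NSN Rnaseh1 and 1.05 for SN mCherry, against 0.62 for NSN mCherry, 0.69 for SN Rnaseh1, and 0.57, 0.35 and 0.42 for Rnaseh1, Rnaseh1 plus Supt6 and mCherry in the rescue set. Part of these differences ran with the GC content of the transcript. The rank correlation across genes with GC content was -0.41 for the difference of the NSN Rnaseh1 replicates, 0.4 for the SN mCherry replicates and -0.5 for Rnaseh1 against mCherry in the rescue set. In the rescue set it took the median log2 fold change from 0.43 in the 10% of genes with the lowest GC content to -1.6 in the 10% with the highest.

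**Figure D2:**
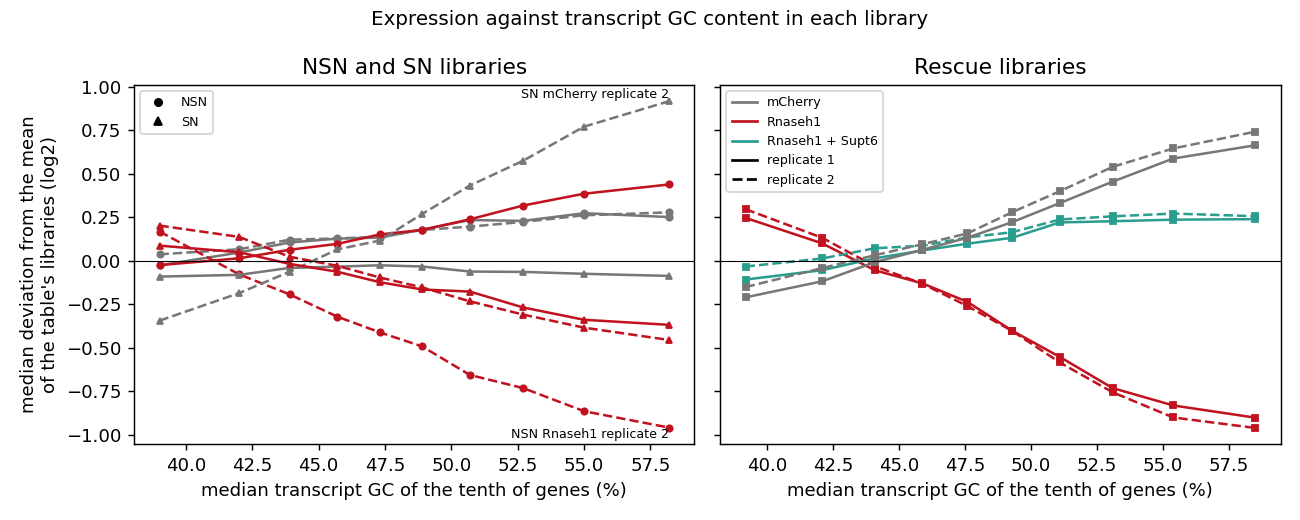
Median deviation of log2(TPM + 1) from the mean of all libraries of the set, over 10 groups of genes ordered by transcript GC content (in percent), one line per library. NSN Rnaseh1 replicate 2 and SN mCherry replicate 2 slope in opposite directions, and both Rnaseh1 libraries of the rescue set slope down towards high GC content.

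In SN oocytes, the later stage, the genes with the smallest p were far apart between Rnaseh1 and mCherry but did not pass over the 12736 genes tested. Mcmbp, which binds the MCM helicase, stood at 170 ± 19.6 TPM with Rnaseh1 against 20.2 ± 4.77 with mCherry (log2 fold change 3.03). The stress kinase gene Mapk8 stood at 135 ± 21.1 against 22.2 ± 2.99 (2.55), the polycomb-group gene Scml2 at 339 ± 34.1 against 51.4 ± 10.1 (2.71), and Copb1, a coatomer subunit, at 1213 ± 315 against 252 ± 0.0354 (2.24). Lower with Rnaseh1 were Ms4a10, at 2.4 ± 0.629 against 19.9 ± 1.92 (-2.63), Ppcdc, an enzyme of coenzyme A synthesis, at 0.775 ± 0.658 against 14.3 ± 0.29 (-3.16), and Adgrl4, at 2.97 ± 0.0707 against 39.3 ± 16.5 (-3.28). The test of limma called 0 genes, with 859 genes at an unadjusted p under 0.05 (466 higher and 393 lower, with 637 expected by chance) and a smallest adjusted p of 0.407. With the replicate number as a block, 561 genes had an unadjusted p under 0.05 in limma, so the excess over chance ended under that choice. The number was 1078 after median centring, 1067 after quantile normalization, 1014 after removal of the GC trend and 1644 with library weights. Each of these fits called 0 genes. The median SE was 0.53, and the median of all genes was -0.22. Without both NSN Rnaseh1 replicate 2 and SN mCherry replicate 2, a choice made after the values were seen, 5 genes passed, of which Rnaseh1 at 3.89 and Mcmbp at 3.26 were higher and Adgrl4 at -3.71 lower, beside the gene models Gm10226 and Gm37750. This fit drops the libraries that differed most and leaves 1 SN mCherry library, so its spread is smaller by construction and comes from the other groups.

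Of the fixed lists 0 passed in SN oocytes. The 5 demethylases of histone H3 lysine 4 (H3K4) lay at a median of 0.98, or 1.19 above all genes (adjusted p = 0.24), with Kdm5a at 1.59, Kdm5c at 0.99 and Kdm1b at 0.98. The mean of this list was 0.6, as the members not named lay lower. The 8 tested enzymes that methylate or demethylate H3 lysine 36 (H3K36) lay at -0.14, 0.07 from all genes (adjusted p = 0.77), and the 16 members of H3K4 methyltransferase complexes at -0.39 (adjusted p = 0.99). Nuclear-encoded oxidative phosphorylation genes (77 tested) lay 0.39 above all genes (adjusted p = 0.11), with Ndufa1 at 1.56 and Ndufv1 at -2.26, and immediate-early and stress genes at -0.6 from them (adjusted p = 0.14), with Hspa8 at -1.2. Oxidative phosphorylation passed without SN mCherry replicate 1 (0.78, adjusted p = 0.00067), without SN Rnaseh1 replicate 2 (0.52, adjusted p = 0.0084) and after removal of the GC trend (0.41, adjusted p = 0.0055), and under quantile normalization the stress genes (-0.72, adjusted p = 0.032) and the oocyte-specific genes (-0.48, adjusted p = 0.015) passed.

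In NSN oocytes, the earlier stage, none of the 12736 genes passed either. The ubiquitin-ligase adaptor gene Btbd1 stood at 33.3 ± 17.7 TPM with Rnaseh1 against 6.87 ± 1.9 with mCherry (log2 fold change 2.04), and Mtrf1l, a mitochondrial translation release factor, and the zinc finger gene Ikzf5 were at 2.04 and 2.01. Eaf2, a partner of the elongation factor ELL, was at 1.55. Lower were Sbf1 at -2.87, Polg, the mitochondrial DNA polymerase, at -1.78, Rpp40, a subunit of RNase P, at -1.83, and Nqo2 at -2.41. Of the maternal genes Khdc3 was at -3.02 and Mos at -2.58. These genes had an adjusted p of 0.76 in limma, which called 0 genes, with 353 at an unadjusted p under 0.05, below the 637 expected by chance. Leaving out NSN Rnaseh1 replicate 1 gave 1152 genes, 99 higher and 1053 lower, so the count rested on which Rnaseh1 library was kept.

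Oxidative phosphorylation was the list that passed in NSN oocytes. Its 77 genes had a median of 0.18 against -0.29 for all genes (adjusted p = 0.00014), though 0 of them passed alone, over all genes or adjusted over the list alone. The complex I subunit Ndufa1 stood at 4810 ± 4083 TPM against 1299 ± 200 (1.57), Atp5mpl was at 1.09, Ndufa4 at 0.96 and Ndufc1 at 0.85. The result did not pass with an estimated correlation (adjusted p = 0.97), and under quantile normalization the list lay 0.21 above all genes (adjusted p = 0.17) while the oocyte-specific genes passed at -0.33 (adjusted p = 0.02). The distance of 0.47 from all genes became 0.22 without NSN Rnaseh1 replicate 2, 0.81 without replicate 1 and 0.29 without a filter, each still past the threshold. The H3K4 demethylases lay 0.63 above all genes (adjusted p = 0.34), the H3K36 enzymes at -0.05 (adjusted p = 0.96) and the meiotic genes at -0.36 (adjusted p = 0.17). The meiotic genes passed at -0.68 without NSN Rnaseh1 replicate 1 (adjusted p = 0.017), and the replication-dependent histones at 0.42 without replicate 2 (adjusted p = 0.00061).

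The difference between the SN and NSN effects of Rnaseh1 was tested directly. For Rnaseh1 itself it was 1.79 (SE 0.8, adjusted p = 1). The largest differences among the genes with the smallest p were Cdkn1c at 2.88, Mcmbp at 2.64, Mapk8 at 2.37, Serbp1 at 2.19 and Copb1 at 2.14 towards SN, and Ms4a10 at -3.42, Styx at -3.3, Ppcdc at -3.02, Ccl1 at -2.96 and Trav3d-3 at -2.12 towards NSN. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, passed when adjusted over the list alone, as 1 of 17 imprinted genes. Over all genes limma called 0, with 288 at an unadjusted p under 0.05 (637 expected by chance) and a median SE of 0.75, and 0 lists passed. The replication-dependent histones came nearest, at -0.57 from all genes (32 tested, adjusted p = 0.11), and passed without SN Rnaseh1 replicate 1 (-0.59, adjusted p = 0.01) or NSN Rnaseh1 replicate 2 (-0.58, adjusted p = 0.018). Oxidative phosphorylation passed without SN mCherry replicate 2 (-0.52, adjusted p = 0.00076) and the meiotic genes without NSN Rnaseh1 replicate 1 (0.42, adjusted p = 0.031).

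Between the stages in mCherry oocytes, which asks what changes from NSN to SN without Rnaseh1, 0 genes passed in limma. An unadjusted p under 0.05 was found for 328, below the 637 expected by chance, of which 53 were higher and 275 lower in SN. The testis- and oocyte-type histone gene Hist1h2ba stood at 16.1 ± 5.13 TPM in SN against 1.03 ± 1.46 in NSN (log2 fold change 3.25), and Ppcdc and Ccl1 were at 1.9 and 1.69. Selenos and Herpud1, of endoplasmic reticulum quality control, were lower in SN, Selenos at 1.55 ± 1.19 against 20.2 ± 0.544 (-3.14) and Herpud1 at -2.86, and Sbf1 and Sdcbp2 were at -2.94 and -2.34. The H3K36 methyltransferase gene Setd2 stood at 25.1 ± 11.8 against 49.2 ± 8.61 (-1.01, adjusted p = 1), the H3K4 demethylase gene Kdm1b at -1.33, Wdr61 of the PAF1 elongation complex at -1.94 and the cell-cycle kinase gene Wee1 at -1.18.

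The 32 replication-dependent histones were the list that passed between the stages, with a median of 0.36 in SN, 0.39 above all genes (adjusted p = 0.0042; adjusted p = 1 with an estimated correlation). Hist1h2bj was at 2.26, Hist1h1a at 1.48 and Hist1h3g at 1.38, and 0 of the 32 passed alone. Near-identical copies make their values uncertain. The distance from all genes dropped to 0.1 without a filter (adjusted p = 0.085), 0.17 with a filter of TPM at least 5 (adjusted p = 0.29) and 0.23 after removal of the GC trend (adjusted p = 0.25), and the call ended. It also ended without SN mCherry replicate 1, at a distance of 0.31 (adjusted p = 0.2). With a pseudocount of 5 (0.17, adjusted p = 0.0061) and without NSN mCherry replicate 1 (0.23, adjusted p = 0.044) the distance dropped and the list passed. Oxidative phosphorylation, at -0.04 from all genes, passed at -0.35 without SN mCherry replicate 1 (adjusted p = 0.043) and at 0.36 without replicate 2 (adjusted p = 0.0024). H3K4 methyltransferase complexes, H3K36 enzymes and transcription elongation factors lay 0.08, -0.1 and 0.03 from all genes, with adjusted p of 0.87, 1 and 0.98.

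In the rescue set most tested genes differed between the Rnaseh1 and the mCherry libraries. Haus1, a subunit of the augmin complex that branches spindle microtubules, rose from 31 ± 1.54 to 560 ± 7.85 TPM (log2 fold change 4.13, SE 0.12, adjusted p = 6.9e-07). The RNA-processing gene Lsm7 rose from 233 ± 9.87 to 3090.0 ± 256 (3.72), Aig1 from 261 ± 15.9 to 3286 ± 68.8 (3.65), Nipsnap2 from 60.1 ± 4.75 to 891 ± 200 (3.85), Vapa, a tether between the endoplasmic reticulum and other membranes, from 11.3 ± 2.04 to 166 ± 18.7 (3.76), and the histone chaperone and phosphatase inhibitor gene Set from 5.08 ± 1.47 to 87.1 ± 7.89 (3.88). Ppme1, which demethylates the phosphatase PP2A, fell from 199 ± 5.7 to 1.97 ± 0.233 TPM (-6.08, SE 0.12, adjusted p = 4.7e-07), the RNA-binding gene Rbm38 from 943 ± 28.2 to 18.4 ± 1.31 (-5.6), and the kinase-like gene Nrbp1, the SUMO ligase gene Pias4, the glycine transporter gene Slc6a9 and the deadenylase subunit gene Cnot3 fell too (-6.19, -5.81, -5.62 and -5.52). Set, Pou5f1, Eif5a and Hspa8 have processed pseudogenes, so their values are uncertain.

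Of 12859 genes tested, 2608 rose and 5945 fell with Rnaseh1, 1614 and 4561 of them at least 2-fold, and the median of all genes was -0.52. Rose made up 30.5% of the calls with TPM as deposited and 48.7% after median centring (3973 rose and 4186 fell), 51.6% after quantile normalization and 48.1% after removal of the GC trend (3428 rose and 3695 fell). Of the calls, 6794 held the same direction after median centring and 5678 after removal of the GC trend. The excess of falls depended on the scaling, and lists are given relative to all genes.

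Oxidative phosphorylation genes rose as a group with Rnaseh1 in the rescue set, 1.42 above all genes (adjusted p = 9.7e-11). This list and the 3 that follow did not pass with an estimated correlation (adjusted p = 0.56 with an estimated correlation for each). Of 77, 53 rose and 17 fell (53 and 18 adjusted over the list alone), among them Ndufa12 of complex I, from 89.6 ± 6.02 to 982 ± 40.7 TPM (3.44), and Cox7c of cytochrome c oxidase, from 365 ± 24.2 to 2614 ± 355 (2.83). Oocyte-specific and maternal-effect genes fell, 28 of 35 with 4 rising, at -0.44 from all genes (adjusted p = 0.0022). The zona pellucida genes Zp1 and Zp3 fell from 1323 ± 81.2 to 122.9 ± 8.16 TPM (-3.42) and from 3080 ± 110 to 575.0 ± 11.7 (-2.42), and Pou5f1 from 256 ± 9.84 to 10.7 ± 1.63 (-4.47), while Dppa3, which protects maternal DNA methylation, rose from 3612 ± 90.3 to 13310 ± 345 (1.88). Meiotic maturation and cell cycle genes fell, 23 of 34 with 3 rising, at -0.63 from all genes (adjusted p = 0.036). Mos, which starts the meiotic MAP kinase cascade, fell from 879 ± 23 to 43.3 ± 2.5 TPM (-4.31), Plk1 from 246 ± 4.62 to 12.8 ± 1.58 (-4.17) and Cdk1 from 225 ± 6.56 to 34.2 ± 2.11 (-2.68), while the securin gene Pttg1 rose from 2286 ± 20.9 to 10330.0 ± 241 (2.17). Of 14 immediate-early and stress genes 13 fell and 0 rose, at -0.97 from all genes (adjusted p = 0.011), with Atf4 at -2.55, Dnajb1 at -2.35, Dusp1 at -2.14 and Hspa8 at -1.5.

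These 4 lists also passed after median centring and quantile normalization, where the oxidative phosphorylation genes numbered 58 rising and 14 falling, the oocyte-specific genes 7 and 24, the meiotic genes 5 and 19 and the stress genes 0 and 10 after centring. Quantile normalization took oxidative phosphorylation from 1.42 to 0.78 above all genes and the oocyte-specific genes from -0.44 to -1.2. The oocyte-specific value also ran from -0.29 with a pseudocount of 0.1 to -0.82 without a filter, the stress value from -1.61 with a pseudocount of 0.1 to -0.29 with one of 5, and the meiotic value was -1.02 without a filter, all past the threshold. The meiotic call ended without Rnaseh1 replicate 1 (-0.54, adjusted p = 0.072) or mCherry replicate 2 (-0.64, adjusted p = 0.05), and the stress call after removal of the GC trend (-0.8, adjusted p = 0.082).

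Lists of chromatin and transcription genes did not pass with Rnaseh1 in the rescue set, where 8553 of all 12859 tested genes were called. Of the 5 H3K4 demethylase genes, Kdm5a rose from 40.8 ± 4.73 to 113 ± 22.7 TPM (log2 fold change 1.44, adjusted p = 0.001), Kdm5c (1.45) and Kdm1b (0.58) also rose, 0 fell, and the list lay 1.1 above all genes (adjusted p = 0.13). In H3K4 methyltransferase complexes 12 of 16 fell and 3 rose (adjusted p = 0.26), and 6 fell and 4 rose after removal of the GC trend (adjusted p = 0.41), with Wdr5, Men1 and Kmt2d at -2.77, -2.51 and -3.01, while Dpy30 rose from 357 ± 10.7 to 1647 ± 31.2 TPM (2.2). Of 11 H3K36 enzymes 7 fell and 1 rose (adjusted p = 0.61), and 3 fell and 2 rose after removal of the GC trend (adjusted p = 0.97), among them the methyltransferase genes Nsd1 (-1.2), Nsd2 (-1.6) and Smyd2 (-2.05). The list lay at -0.55 from all genes, and at 0.27 after removal of the GC trend. Of 30 elongation factors 15 fell and 7 rose (adjusted p = 0.7), and 10 fell and 9 rose after median centring (adjusted p = 0.66). Nelfa of the pausing complex fell from 135 ± 4.93 to 10.1 ± 1.77 TPM (-3.62), and Ell and Ccnt1 fell by 3.95 and 3.04 on the log2 scale. DNA methylation genes fell in 9 cases of 13 and rose in 3 (adjusted p = 0.41), with Uhrf1 at -3.54 and Dnmt3l at -3.23.

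R-loop processing factors fell in 14 cases of 25 and rose in 2 with Rnaseh1 (adjusted p = 0.41), and 8 fell and 7 rose after median centring (adjusted p = 0.65). Top3b fell by 3.48 and Rpa1 by 2.31 on the log2 scale. DNA repair genes fell in 20 cases of 31 and rose in 2 (adjusted p = 0.2), and 13 fell and 7 rose after median centring (adjusted p = 0.38), with H2ax at -4.19. Of 17 p53 target genes 8 fell and 0 rose (adjusted p = 0.2), with Bax at -2.83. Maternal mRNA storage and decay genes fell in 16 cases of 27 and rose in 4 (adjusted p = 0.13), with Pabpn1l at -2.42 and Cpeb1 at -2.66; after removal of the GC trend this list passed at -0.73 (adjusted p = 0.0056). Interferon-stimulated and nucleic-acid sensing genes fell in 7 cases of 11 (adjusted p = 0.41), and in 3 after median centring (adjusted p = 0.38), with Irf1 at -2.69 and Adar at -3.04, while Cgas rose by 1.04. Of 17 imprinted genes 5 rose and 5 fell (adjusted p = 0.41), and 7 rose and 3 fell after median centring (adjusted p = 0.49), with Mest at -2.44 and Gnas at 1.07. Of 24 replication-dependent histones 11 fell and 2 rose (10 and 1 adjusted over the list alone; adjusted p = 0.7), and 2 fell and 3 rose after median centring (adjusted p = 0.69). Of 9 genes of the 2-cell embryo 4 fell and 1 rose (adjusted p = 0.86), and 4 fell and 3 rose after median centring (adjusted p = 0.97). The deposited values hold 6 cytoplasmic ribosomal protein genes and none of the numbered Rpl and Rps genes, so most of that family is missing. Of these, 2 of the 6 fell and 1 rose (adjusted p = 0.7), and 2 fell and 4 rose after median centring (adjusted p = 0.51). The 2-cell list lay 0.42 above all genes by its median, while its mean was -0.39 and its test pointed down, and the ribosomal list had a median of 0.03 and a mean of -0.37. Of 2 Hox and Pax genes 1 fell, Hoxa7 at -1.81. Mitochondrially encoded mRNAs had 0 tested genes. Adjusted over the list alone, 1 of the Hox and Pax genes rose and 1 fell, and the counts of the other lists given here without a count over the list alone were the same both ways.

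With Supt6 added to Rnaseh1, the comparison with mCherry asks what stays changed in the rescue. The Notch regulator gene Dtx2 fell from 323 ± 15.2 to 61.0 ± 1.88 TPM (log2 fold change -2.39, SE 0.1, adjusted p = 0.00093), Mier2 from 103 ± 0.742 to 17.0 ± 0.863 (-2.53), the peroxisome gene Pex14 from 81.8 ± 1.64 to 12.7 ± 0.919 (-2.6), and the autophagy gene Atg9a by 2.78 on the log2 scale. Khdc3, of the maternal subcortical complex, rose from 35.7 ± 4.21 to 152 ± 53.5 TPM (2.02), the clock gene Per3 from 41.4 ± 15.6 to 136 ± 27.2 (1.73), the zinc transporter gene Slc30a9 by 2.03 and Lsm4 by 1.58. In all 734 genes rose and 977 fell, 96 and 487 of them at least 2-fold, with a median of -0.04. Rose made up 42.9% of the calls and 59.1% after removal of the GC trend (1369 calls). The count ran from 85 without Rnaseh1 plus Supt6 replicate 2 and 146 without replicate 1, over 201 and 320 without mCherry replicates 2 and 1, to 2726 and 2712 without Rnaseh1 replicates 1 and 2.

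Oxidative phosphorylation was again the list that passed, 0.38 above all genes (adjusted p = 1.9e-13, and adjusted p = 0.81 with an estimated correlation). Under quantile normalization it lay 0.22 above (adjusted p = 2.2e-07). The log2 fold changes also ran with transcript length (rank correlation -0.21 across genes), a trend that was not removed. Of 77, 33 rose and 3 fell (45 and 5 adjusted over the list alone), with Uqcr11 of complex III from 491 ± 24.6 to 1008 ± 19.1 TPM (1.04) and Ndufa12 from 89.6 ± 6.02 to 201 ± 19.8 (1.16). Setd2 rose from 41.1 ± 4.99 to 74.1 ± 1.77 TPM (0.84, adjusted p = 0.021), while the H3K36 demethylase genes Kdm2a (-1.16) and Kdm2b (-0.62) fell, as 1 rising and 2 falling of 11 H3K36 enzymes (1 and 3 adjusted over the list alone). Dpy30 rose by 0.55 and 5 of 16 genes of H3K4 methyltransferase complexes fell (2 and 6 adjusted over the list alone), with Kmt2d at -1.33 and Men1 at -1.02. Kdm5a fell by 0.86 on the log2 scale (adjusted p = 0.048), a call that ended after median centring, quantile normalization and removal of the GC trend, where 0 of the 5 H3K4 demethylases passed. Oocyte-specific genes split into 8 rising and 11 falling of 35 (8 and 14 adjusted over the list alone), with Dppa3 at 0.78 and Rfpl4 at -0.83. Meiotic genes split into 3 and 8 of 34 (3 and 9 adjusted over the list alone), with Pttg1 at 0.98 and Plk1 at -0.79. Nelfa and Ell stayed lower, at -1.3 and -1.6, and Uhrf1 at -1.76.

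Between Rnaseh1 plus Supt6 and Rnaseh1 alone, most of the genes changed by Rnaseh1 moved back towards their level with mCherry. Rln3 rose from 3.0 ± 1.46 to 199 ± 5.63 TPM (log2 fold change 5.69, SE 0.23, adjusted p = 3.1e-06), Ppme1 from 1.97 ± 0.233 to 111 ± 3.66 (5.25) and the translation factor gene Eif5a from 11.9 ± 0.453 to 457 ± 18.2 (5.15). Nrbp1 and the phosphatidylinositol synthase gene Cdipt rose by 5.47 and 4.94. Haus1 fell from 560 ± 7.85 to 51.7 ± 6.82 TPM (-3.42), the chemokine gene Ccl2 from 129 ± 7.53 to 12.9 ± 2.6 (-3.23) and Vapa from 166 ± 18.7 to 19 ± 3.07 (-3.07). In all 5343 genes rose and 2235 fell, 3843 and 1201 at least 2-fold, with a median of 0.44 over 12859 genes. Rose made up 70.5% of the calls, and 49.2% after median centring, 48.1% after quantile normalization and 50.5% after removal of the GC trend.

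The same 4 lists passed as with Rnaseh1 against mCherry, each in the opposite direction, and none with an estimated correlation (adjusted p = 0.56 with an estimated correlation for each). Both comparisons hold the same Rnaseh1 libraries with opposite sign. A list displaced in those libraries is pushed the opposite way here, so these calls are not independent of the first. Of the oocyte-specific genes 25 of 35 rose and 4 fell (0.53 above all genes, adjusted p = 0.0081), with Zp3 from 575.0 ± 11.7 to 3956 ± 138 TPM (2.78), the growth factor gene Gdf9 from 1277 ± 152 to 7269 ± 180 (2.51) and the oocyte linker histone gene H1f8 from 2065 ± 10.7 to 9406 ± 484 (2.19). Of the meiotic genes 20 of 34 rose and 3 fell (0.63 above, adjusted p = 0.037), with Mos from 43.3 ± 2.5 to 675 ± 4.21 TPM (3.93), Plk1 at 3.38 and Cdk1 at 2.61. Of the stress genes 11 of 14 rose and 0 fell (0.91 above, adjusted p = 0.019), with Dnajb1 at 2.37 and Hspa8 at 1.6. Of the oxidative phosphorylation genes 45 of 77 fell and 21 rose (46 and 21 adjusted over the list alone; -0.85 from all genes, adjusted p = 1e-07), with Cox7c from 2614 ± 355 to 536 ± 8.49 TPM (-2.28), Ndufa12 at -2.28 and Ndufa10 at 2.03. Quantile normalization took the oocyte-specific genes to 1.15 above all genes and oxidative phosphorylation to -0.44. Without a filter oxidative phosphorylation lay at -0.52, the meiotic genes at 0.96 and the stress genes at 0.42 from all genes, and with a pseudocount of 5 the stress genes at 0.37. Without Rnaseh1 replicate 1 the meiotic (0.52, adjusted p = 0.072) and stress (0.99, adjusted p = 0.059) calls ended. The meiotic call also ended without Rnaseh1 plus Supt6 replicate 2 (0.52, adjusted p = 0.05) and with a filter of TPM at least 5 (0.61, adjusted p = 0.058), and the stress call after removal of the GC trend (0.39, adjusted p = 0.17).

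Among chromatin genes, Kdm5a fell from 113 ± 22.7 to 22.4 ± 6.44 TPM (-2.3) with Supt6 added, and Kdm5c (-1.52) and Kdm1b (-0.71) fell too, 3 of 5 H3K4 demethylases (adjusted p = 0.098). Of H3K4 methyltransferase complexes 11 of 16 rose and 2 fell (adjusted p = 0.4), and 3 rose and 3 fell after removal of the GC trend (adjusted p = 0.75), with Wdr5 at 1.95 and Dpy30 at -1.65. Nsd2 (2.08), Smyd2 (2.07) and Nsd1 (1.13) rose, with 4 of 11 H3K36 enzymes rising and 1 falling (3 and 1 adjusted over the list alone), and 3 rising and 4 falling after removal of the GC trend (adjusted p = 0.88). Nelfa rose from 10.1 ± 1.77 to 54.1 ± 0.757 TPM (2.32), and Dnmt3l by 3.03.

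**Figure D3:**
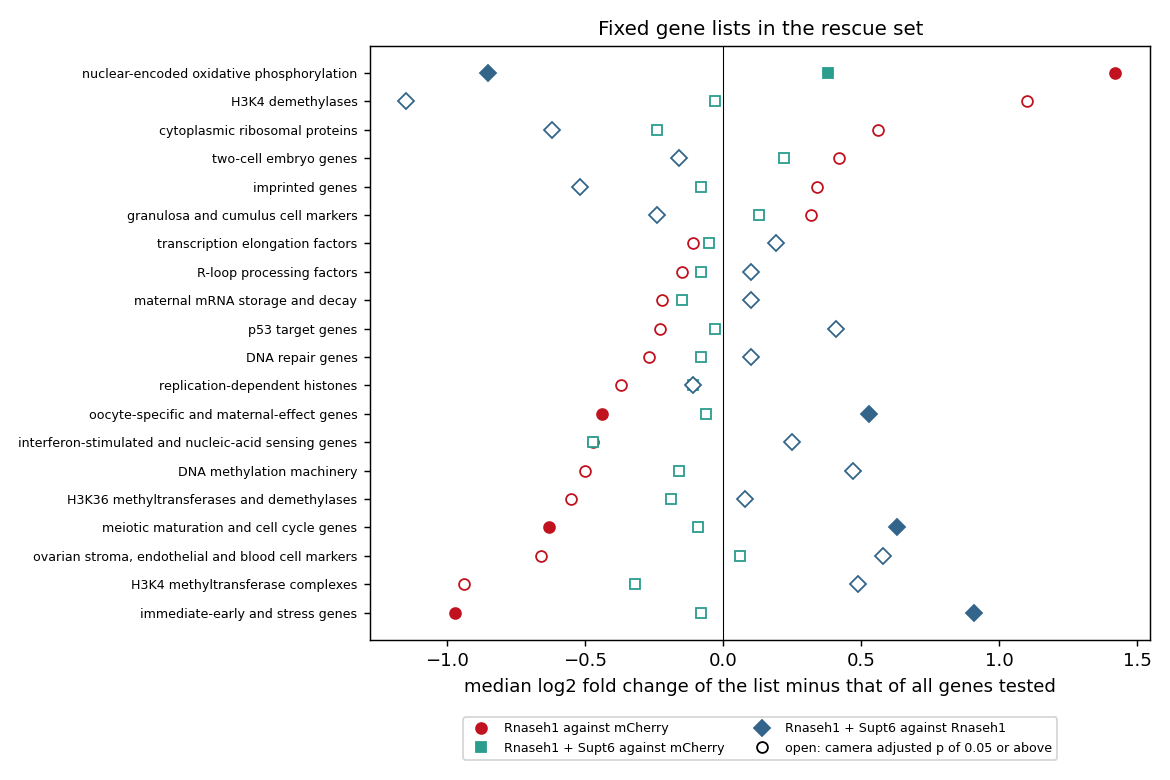
Median log2 fold change of 20 fixed gene lists minus the median of all tested genes, in the 3 comparisons of the rescue set, filled where camera with its preset correlation gave an adjusted p under 0.05. Oxidative phosphorylation lies at 1.42, 0.38 and -0.85, and the oocyte-specific, meiotic and stress lists lie below 0 with Rnaseh1 and above 0 when Supt6 is added.

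The 3 comparisons of the rescue set were set side by side gene by gene. Of the 5945 genes that fell with Rnaseh1, 4947 (83.2%) rose when Supt6 was added, 906 (15.2%) were still lower than mCherry and 118 were higher. Independent lists would share 2470 genes in the first of these counts. Both lists rest on the same Rnaseh1 libraries with opposite sign, so more would be shared without any effect. The number for independent lists is therefore too low a reference. Of the 2608 genes that rose, 2029 (77.8%) fell when Supt6 was added, 531 (20.4%) were still higher than mCherry and 9 were lower. Fewer genes differed from mCherry when any library of either group was left out. Such a fit leaves a lone library in its group and has less power. The drop therefore does not show that the 906 and 531 rest on a single library. The median of the genes that fell went from -1.52 with Rnaseh1 to -0.27 with both, and that of the genes that rose from 1.17 to 0.31. Comparisons that share libraries correlate without any effect. The effect of Rnaseh1 and the later change with Supt6 had r = -0.94 with a covariance of -1.59, where unchanged groups gave -0.5 and -0.052 over 100 draws. The effects of Rnaseh1 and of both genes against mCherry had r = 0.59 with a covariance of 0.43, against 0.5 and 0.052. With separate libraries on each side, over 4 choices, the first relation had r from -0.85 to -0.83 and the second from 0.45 to 0.51.

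Across the 11800 genes of both sets, the effect of Rnaseh1 in the rescue set ran with that in SN oocytes at r = 0.69 and with that in NSN oocytes at 0.55, and the SN and NSN effects with each other at 0.54. These values rested on 2 libraries. With NSN Rnaseh1 replicate 2 and SN mCherry replicate 2 left out, a choice made after the values were seen, they were 0.28, -0.04 and -0.02. Without NSN Rnaseh1 replicate 2 alone the NSN values were -0.04 and -0.02, and without SN mCherry replicate 2 alone the SN values were 0.28 with the rescue set and 0.3 with NSN oocytes. The rescue effect also correlated with the plain difference between the libraries of some groups, at 0.63 for NSN Rnaseh1 replicate 2 minus 1 and -0.74 for SN mCherry replicate 2 minus 1, against 0.21 for NSN mCherry and -0.04 for SN Rnaseh1.

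Sets of 200 genes taken from the NSN and SN oocytes were followed in the rescue set. Genes higher with Rnaseh1 in SN oocytes had a median of 0.97 with Rnaseh1 in the rescue set, 131 rising and 10 falling (adjusted p = 6.9e-23; adjusted p = 0.071 with an estimated correlation), and those lower in SN oocytes had -1.55, 7 rising and 142 falling (adjusted p = 7.3e-06; adjusted p = 0.071 with an estimated correlation). Genes higher with Rnaseh1 in NSN oocytes had 1.13, 117 rising and 6 falling (adjusted p = 1.9e-19; adjusted p = 0.065 with an estimated correlation), and those lower had -0.56 (adjusted p = 0.58). Transcript GC content stood at 43.4% for the SN higher set, 51.9% for SN lower, 45.4% for NSN higher and 48.8% for NSN lower. The median of all genes tested in the rescue set was 48.4%. The rescue effect had a rank correlation of -0.5 with GC content, so a shared GC trend may contribute to these medians. When Supt6 was added, the genes higher in SN oocytes fell back by 0.8 on the log2 scale, with 125 falling and 9 rising (adjusted p = 2.3e-23, and adjusted p = 0.071 with an estimated correlation). That comparison shares the rescue Rnaseh1 libraries, so it is not independent of the rise. Genes lower in SN than in NSN mCherry oocytes had a median of 0.11 with Rnaseh1, 0.63 above all genes (adjusted p = 2e-04; adjusted p = 0.17 with an estimated correlation), and genes higher had -0.51 (adjusted p = 0.75). The distance of the genes lower in SN was 1.29 without SN mCherry replicate 1. It was 0.06 without replicate 2 and 0.27 after removal of the GC trend, where the call ended. It turned to -0.69 without both NSN Rnaseh1 replicate 2 and SN mCherry replicate 2. Of the 18 tests 11 passed, and 0 with an estimated correlation. The SN lower set turned from -1.55, or -1.03 from all genes, to 0.18 above all genes without SN mCherry replicate 2, and the NSN lower set to 0.33 above all genes without NSN Rnaseh1 replicate 2. The NSN higher set lay 1.65 above all genes, and 0.47 above without NSN Rnaseh1 replicate 2. The genes higher in SN than in NSN went from 0.01 to -1.72 from all genes without SN mCherry replicate 1 and to 1.21 without replicate 2.

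Markers of other ovarian cells were followed in every library. The granulosa cell genes Inha, Amh, Foxl2 and Wt1 were listed at 0 in all libraries of the NSN and SN set, and in the rescue set Inha was at most 0.33 TPM and the others were listed at 0. From 3 to 6 of 20 granulosa and cumulus cell markers and from 3 to 5 of 19 stroma, endothelial and blood cell markers had a TPM of at least 1 per library. Cyp19a1 lay between 13.0 and 46.1 TPM in the NSN and SN set and between 38.1 and 44.9 in the rescue set, where it did not pass with Rnaseh1 (-0.03). Serpine2 fell with Rnaseh1 from 395 ± 34.7 to 48.3 ± 6.7 TPM (-3.01), as did Pecam1 (-1.96) and Cd68 (-2.09), and Serpine2 rose by 3.12 with Supt6 added, the directions of the oocyte-specific genes. In that set 1 of 4 tested granulosa markers (adjusted p = 0.82) and 2 of 4 stroma, endothelial and blood markers (adjusted p = 0.61) fell with Rnaseh1. After median centring 1 granulosa marker fell and 2 rose.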

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

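The tests of explanations below were all chosen after the patterns were seen; the test of the difference between the SN and NSN effects was chosen before.

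Both SN libraries with Rnaseh1 moved one way from their mCherry controls and both NSN libraries the other way, without overlap, for 6 named genes. These 6 came from the genes with the smallest p for this same difference. The share of all genes with such a pattern was not counted. Cdkn1c, an imprinted cell-cycle inhibitor, went from 2.1 and 2.7 TPM to 12.0 and 9.24 in SN oocytes and from 8.49 and 6.8 to 2.71 and 3.26 in NSN oocytes, a difference of 2.88 on the log2 scale. Serbp1, which binds mRNA and ribosomes, differed by 2.19 in the same direction. Ms4a10 (-3.42), the pseudophosphatase gene Styx (-3.3), the chemokine gene Ccl1 (-2.96) and the T cell receptor segment gene Trav3d-3 (-2.12) differed the other way. The adjusted p of limma's test of the difference was 1 for each, so none is shown to differ between the stages.

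NSN Rnaseh1 replicate 2 and SN mCherry replicate 2 stood apart from the other library of their group. Exchanged treatment labels are argued against by Rnaseh1 itself, which in NSN Rnaseh1 replicate 2 was 1.67 times the highest mCherry library of the set. In SN mCherry replicate 2 it lay below every Rnaseh1 library. The level of Rnaseh1 says nothing of exchanged stage labels. NSN Rnaseh1 replicate 2 correlated at r = 0.925 and 0.912 with the SN Rnaseh1 libraries and at 0.865 with its partner. Those SN libraries correlated at 0.963 with each other. SN mCherry replicate 2 correlated at 0.938 and 0.926 with the NSN mCherry libraries and at 0.908 with its partner. Those NSN libraries correlated at 0.967 with each other. On the first principal component NSN Rnaseh1 replicate 2 lay at 113, beyond the SN Rnaseh1 libraries at 39.9 and 35.9. SN mCherry replicate 2 lay at -91, beyond the NSN mCherry libraries at -40.7 and -25.5. These values argue against exchanged stage labels as the whole source of the distance. GC-dependent recovery as the whole source is argued against because the SD of the replicate difference was still 0.97 for SN mCherry and 1.18 for NSN Rnaseh1 with the GC trend removed, against at most 0.69 for the other groups. Granulosa or cumulus cells are argued against because 14 of 20 of their markers were under 1 TPM in both libraries, with Inha, Amh and Foxl2 listed at 0, while 6 genes that every cell uses (Actb, Gapdh, Eef1a1, Ppia, Hprt and Tbp) were at 8.33 TPM or more in every library. A failure to estimate Inha, Amh and Foxl2 alone cannot be excluded from TPM, and Cyp19a1 (13.0 to 46.1 TPM) and Serpine2 (38.8 to 381 TPM) were present in every library of the set. A difference in oocyte quality, exact stage or amplification between libraries stays open, and no biological explanation was tested.

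The broad change with Rnaseh1 in the rescue set ran along the same axis of genes. With the GC trend removed from the log values 7123 genes passed, 5678 of them called in the same direction without that step, and after median centring 8159 did, 6794 of them in the same direction, which argues against GC-dependent recovery and against rescaling by a few abundant transcripts as whole causes. With the GC trend removed, the effect correlated across genes at r = -0.68 with SN mCherry replicate 2 minus replicate 1, libraries that carry the same label. The same value was 0.55 for NSN Rnaseh1, 0.23 for NSN mCherry and -0.09 for SN Rnaseh1. A property of the libraries other than the overexpressed RNA may therefore contribute. It cannot be told apart from an effect of Rnaseh1 because both libraries of a rescue group would share it. Between the sets, SN mCherry replicate 1 had r = 0.941 and 0.943 with rescue Rnaseh1 and 0.858 and 0.849 with rescue mCherry. With replicate 1 of the rescue groups, NSN mCherry replicates 1 and 2 leaned the same way, at 0.896 and 0.917 for Rnaseh1 against 0.888 and 0.877 for mCherry. SN mCherry replicate 2 went the other way, at 0.834 against 0.944. These values do not say which rescue group is set apart. The removal of R-loops by Rnaseh1, inferred from what its protein does and not named in the labels, stays open as a hypothesis.

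The libraries with Rnaseh1 plus Supt6 lay near the mCherry libraries. Less Rnaseh1 RNA is argued against, since Rnaseh1 was 1.28 higher on the log2 scale than with Rnaseh1 alone (adjusted p = 0.0062). If the Rnaseh1 libraries alone were set apart by their preparation and Rnaseh1 itself did nothing, the libraries with both genes would keep none of the change. The slope of what they kept on the Rnaseh1 change was 0.17 to 0.19 over 4 choices of separate libraries. This slope cannot decide the question. The libraries with both genes also carry Rnaseh1 RNA and could keep part of its effect whatever the preparation. A property shared by both mCherry libraries would also give a positive slope. An action of Supt6 against the effect of Rnaseh1 may account for the return and cannot be told apart from such a preparation effect, because the labels do not say which libraries were prepared together. The deposited values hold no protein amounts.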

How the results depend on the processing

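Removal of the GC trend, library weights and the fit without both set-apart libraries (NSN Rnaseh1 replicate 2 and SN mCherry replicate 2) were chosen after the results were seen, and the other alternatives before the data were examined. Where no reason is given, the cause was not tested. TPM keeps no depth, so what depth limits could not be computed.

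Over all alternatives, values of the fixed lists kept their direction and side of the threshold in 2751 cases, ended a call in 23, gained one in 27 and reversed in 3. Most lists did not pass in the main fit, so most of the 2751 cases are lists that stayed outside the threshold. The tally does not measure how stable the passing lists were. For named genes the counts were 2049, 44, 9 and 1, and for the gene sets in the rescue set 427, 45, 38 and 12. The total of genes in the rescue set for Rnaseh1 against mCherry stayed within 1.5 times the main count under every alternative, while the 2608 that rose became 4223 with quantile normalization and the 5945 that fell became 3695 with the GC trend removed.

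Without a filter, 927 genes passed for Rnaseh1 plus Supt6 against mCherry, 7 lists passed for Rnaseh1 against mCherry (adding mRNA storage, DNA repair and p53 target genes), 7 of 18 gene sets and 0 lists between the stages. With a filter of TPM at least 5, 0 lists passed between the stages. With quantile normalization 2 lists passed in SN oocytes, and in NSN oocytes the oocyte-specific genes passed in place of oxidative phosphorylation. A minimum log2 change of 1, which by its construction removes genes, left 583 genes for Rnaseh1 plus Supt6 against mCherry and 5044 against Rnaseh1. With an estimated correlation 0 lists passed in NSN oocytes, between the stages and in the 3 rescue comparisons, and 0 gene sets. Over genes with a mean TPM of at least 10 the SN and NSN effects agreed at r = 0.7 and the rescue and NSN effects at 0.69.

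With the GC trend removed, 1 list passed in SN oocytes, 2 in NSN oocytes and 0 between the stages, and Supt6 with Rnaseh1 alone turned to 0.92. The histone value of the rescue set is void there, as most of its symbols had no GC value. In the rescue set oxidative phosphorylation, oocyte-specific and meiotic genes passed as before, maternal mRNA storage genes passed too (-0.73, adjusted p = 0.0056), and the 6 ribosomal protein genes in the deposited values, a small part of the family, passed at -1.33 when Supt6 was added. With library weights 2907 genes passed for Rnaseh1 plus Supt6 against mCherry.

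Without both set-apart libraries, where 2 groups keep 1 library each and the spread comes from the other groups, 5 genes passed in SN oocytes and 2 for the difference (the gene models Gm10226 at -10.09 and Gm37750 at -12.38), with 2 lists in NSN oocytes, 3 between the stages and 2 for the difference. Between the stages, oxidative phosphorylation turned to 0.36 and oocyte-specific genes to -0.23 from all genes. The agreement became -0.02 for SN and NSN, 0.28 for the rescue set and SN, and -0.04 for the rescue set and NSN. Relative to all genes, with Rnaseh1 against mCherry the NSN lower set turned to 0.38 and the stage lower set to -0.69. With both genes against mCherry the SN lower set turned to 0.15 and the stage higher set to 0.27. With both genes against Rnaseh1 the NSN lower set turned to -0.33 and the stage lower set to 0.83.

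With each library left out in turn, the lone library of its group was assumed to vary like the others. The number of genes ran from 0 to 0 in SN oocytes and between the stages, 0 to 1152 in NSN oocytes, 0 to 1 for the difference (Gm10226), 7080 to 8460 for Rnaseh1 against mCherry, 85 to 2726 for both genes against mCherry and 5630 to 7538 for both genes against Rnaseh1. The number of lists ran from 0 to 1 (SN), 1 to 2 (NSN), 1 to 2 (stages), 0 to 1 (difference), 3 to 4, 1 to 1 and 2 to 5 (rescue comparisons in the same order), and that of gene sets from 6 to 15. The agreement ran from -0.02 to 0.62 for SN and NSN, 0.28 to 0.78 for the rescue set and SN, and -0.04 to 0.63 for the rescue set and NSN. Oxidative phosphorylation between the stages ran from -0.35 to 0.36 and oocyte-specific genes from -0.24 to 0.32. With Rnaseh1 against mCherry the SN lower set ran from -2.13 to 0.18, NSN lower from -0.83 to 0.33, stage higher from -1.72 to 1.21 and stage lower from 0.06 to 1.29. With both genes against mCherry, SN lower ran from -0.26 to 0.12 and stage higher from -0.4 to 0.17. With both genes against Rnaseh1, NSN lower ran from -0.23 to 1.13, stage higher from -1.18 to 1.25 and stage lower from -1.02 to 0.06. Supt6 with Rnaseh1 alone ran from -0.25 to -0.07.

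With the replicate number as a block, 0 genes passed in each of the 4 comparisons of NSN and SN oocytes, and 8517, 1583 and 7535 in the rescue comparisons. Deviations of libraries with the same number correlated at -0.51 to 0.17 in the NSN and SN set and at 0 to 0.04 in the rescue set. The -0.51 is between the groups of the set-apart libraries. These values cannot show whether a shared number marks a shared animal, day or batch, which the labels do not say.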

Other observations

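The families below were defined from symbols after the values were seen, 15 families in 6 comparisons, and adjusted over all 90 tests, and none passed with an estimated correlation (adjusted p of 0.89 to 0.99 for those named). In the rescue set the LSM and SNRP genes, whose proteins form the rings of spliceosomal and mRNA-decay particles, rose with Rnaseh1 in 16 of 25 cases and fell in 6, at 1.31 above all genes (adjusted p = 0.00042). With Supt6 added, 13 of them fell and 5 rose against Rnaseh1 alone (adjusted p = 0.001), a comparison that shares the Rnaseh1 libraries. Against mCherry 5 of the 25 rose and 0 fell (adjusted p = 0.02). Solute carriers fell with Rnaseh1, 113 of 183 with 16 rising, at -0.57 from all genes (adjusted p = 0.044).

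With Rnaseh1 plus Supt6 against mCherry, 4 of the 15 families passed. The log2 fold changes of this comparison had a rank correlation across genes of -0.21 with transcript length and -0.32 with GC content. The difference between the 2 rescue mCherry replicates had 0.18 with length. Whether these trends account for the families was not tested. The 734 genes that rose in this comparison became fewer when any library of either group was left out. Such a fit leaves a lone library in its group and has less power. The counts of family members rest on the same calls. Mitochondrial ribosomal proteins rose in 19 of 77 cases and fell in 2, at 0.22 above all genes (adjusted p = 9.7e-05). Proteasome subunits rose in 9 of 46 cases and fell in 0 (adjusted p = 0.011), LSM and SNRP proteins in 5 of 25 and 0 (adjusted p = 0.02), and RNA polymerase II subunits in 5 of 13, with 0 falling (adjusted p = 0.032). Translation initiation factors (-0.01 from all genes, 3 rising and 8 falling of 51) and Mediator subunits (-0.03, 3 and 5 of 31) had an adjusted p of 0.97, mitochondrial import proteins 0.71, V-ATPase subunits 0.23 and CCT chaperonin subunits 0.19. In NSN oocytes the proteasome subunits lay at -0.31 from all genes with Rnaseh1 (adjusted p = 0.035). Between the stages in mCherry oocytes, Zfp zinc finger genes (248 tested) lay at -0.19 from all genes (adjusted p = 0.0023). None of these genes passed alone in the NSN and SN oocytes.

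The 100 most abundant genes took 30.1% to 43.0% of all TPM in the NSN and SN set, with NSN Rnaseh1 replicate 2 the highest, and 31.1% to 35.4% in the rescue set.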
